A study of Mus musculus with 24 samples.

How the data were processed

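The intestines of Amacr knockout and wild-type mice were rinsed with saline of 0.85% and cut into 4 segments, and the layer scraped from each opened segment gave total RNA, per the labels' protocols. The labels name the cell type of that layer endothelial, and whether epithelial is meant is open. The RNA was labelled with biotin and measured on one-colour arrays, 1 array per sample. The values used here are the authors' deposited log2 values, made with RMA per the submitters' processing notes; the version is not given in the sources used here. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set, so that differences in total RNA between samples are removed and low values are compressed. The base of the logarithm is not stated; log2 is what RMA returns, and folds given here rest on it. The values hold 2 decimals. All 24 columns matched a sample, and 0 other sample columns were present.

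Of 16556 probe sets, 15270 name 1 gene, 0 name several, 64 are controls of the array and 1222 have no name in the table used here. Symbols were looked up by gene number in a RefSeq table of GRCm38.p6, and 0 symbols changed; its coordinates were used only for which genes neighbour Amacr, since the build of the probe design is not given. For 3 genes with 2 probe sets, the one with the higher mean was kept, which left 15267 genes. No filter on dim genes was applied. Array medians ranged from 6.06 to 6.16 and the values from 2.92 to 14.74. The signal of the 3' probe set exceeded that of the 5' probe set by 0.38 to 1.02 for actin controls and by -0.15 to 0.17 for Gapdh controls. Arrays of a group correlated at 0.979 to 0.995 over genes, and 0 pairs of arrays held identical values.

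Before the data were examined, the groups (genotype by segment, 8 groups of 3), tests, gene lists and alternatives were fixed. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 24 arrays with a mean per group, with 16 residual degrees of freedom and a prior of 3.35. The genotype difference over the intestine was tested on the mean of the 4 segments per replicate number, 3 against 3. The labels number the samples of each genotype 1 to 3 in every segment but do not state that a number marks 1 mouse; the means assume it. The interaction was tested with limma's moderated F test over 3 contrasts. P-values were adjusted by Benjamini-Hochberg, with calls at 0.05. The labels call the samples biological replicates. Lists with at least 5 measured members, 38 of 39, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The list left untested holds markers of red blood cells, with 4 measured members. The lists comprised 19 pathways or regions of the intestine and 20 sets of cell type markers.

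The text names, for every genotype comparison, a set of 16 planned genes of sterol and bile acid handling (13 of them measured, the other 3 not analysed here), the 10 largest rises and falls past the threshold, the 10 of segment 4 against segment 1 in each direction, the 3 of each step between neighbouring segments, and up to 4 called members per list; symbols that are only clone, locus or predicted-gene names (Gm and a number, an ending in Rik, LOC and the like) were counted but passed over. The planned genes of a comparison are given in part as a range. Members of a list named without passing the threshold, Sub1, Epcam, Vil1 and the clock genes were chosen after their values were seen. Alternatives were median centring, renewed quantile normalization, 2 filters on dim genes (12158 and 8485 genes left), the mean of probe sets, eBayes with trend and robust, array weights, blocks for the replicate number, the arrays of 1 segment alone and each replicate left out. After the data were seen, 3 more were added: leaving out the 5 arrays whose fat, smooth muscle or pancreas markers lay over 1 log2 above the mean of all arrays, these marker means as covariates, and all probe sets but controls. The test of lists for a genotype difference that varies by segment (114 tests) was also added then.

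The steps were tested on simulated values for the 15267 genes, with each gene's own spread and 200 genes changed. Simulated genes varied independently of each other, and no simulated array held RNA of other tissues. The shares recovered may thus be too high, and the false calls too few, for the real arrays. For the genotype comparison in segment 1, 58.2%, 92.5% and 100% of genes changed by 0.5, 1 and 2 log2 were recovered. False calls numbered 4 there and from 4 to 13 over all comparisons. For the mean of 4 segments, in which the simulation puts no variation between mice, 85.1%, 97% and 100% were recovered. For the interaction these shares were 17.9%, 85.1% and 98.5%, and for segment 4 against 1 in the wild-type 52.2%, 89.6% and 100%.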

Results

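RNA from the intestine of Amacr knockout and wild-type mice was measured on 24 one-colour arrays. Amacr encodes alpha-methylacyl-CoA racemase, an enzyme of peroxisomes that takes part in bile acid synthesis and in the breakdown of branched-chain fatty acids. Each intestine had been cut into 4 segments of equal size, here numbered as in the labels, and 3 biological replicates were measured per genotype and segment, in 8 groups. The mice were male, 3 to 3.5 months old and of the strain C57BL/6 per the labels. The series takes the place of cholesterol absorption in the intestine as its background and compares expression between the genotypes in each segment. After 1 probe set per gene was kept, 15267 genes were compared. Array medians lay between 6.06 and 6.16 on the log2 scale. The number of arrays, 3 per group, limits the precision of every value.

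Amacr itself was lower in the arrays labelled knockout in every segment. Its level was 8.42 ± 0.34 in wild-type and 5.34 ± 0.21 in knockout arrays of segment 1 (mean ± SD, n = 3), and 7.03 ± 0.08 against 4.96 ± 0.15 in segment 4. The log2 differences were -3.08 (SE 0.19, adjusted p = 1.26e-08), -2.84 (SE 0.19, adjusted p = 5.44e-08), -1.95 (SE 0.19, adjusted p = 1.85e-05) and -2.08 (SE 0.19, adjusted p = 6.47e-06) in segments 1 to 4, by limma with Benjamini-Hochberg adjustment, where changes are knockout minus wild-type throughout. The part of the gene that the probes match is not given in the sources used here, so this checks the labels only if it covers the deleted part. The labels call the scraped layer endothelial. Epcam and Vil1, genes of epithelium, stood at 13.41 ± 0.08 and 13.39 ± 0.03 (log2, mean ± SD, n = 3) in wild-type segment 1, near the top of the arrays' range. These levels argue that the layer held much epithelium, though what the label means is not stated. They do not show how much vessel endothelium it held.

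**Figure D1:**
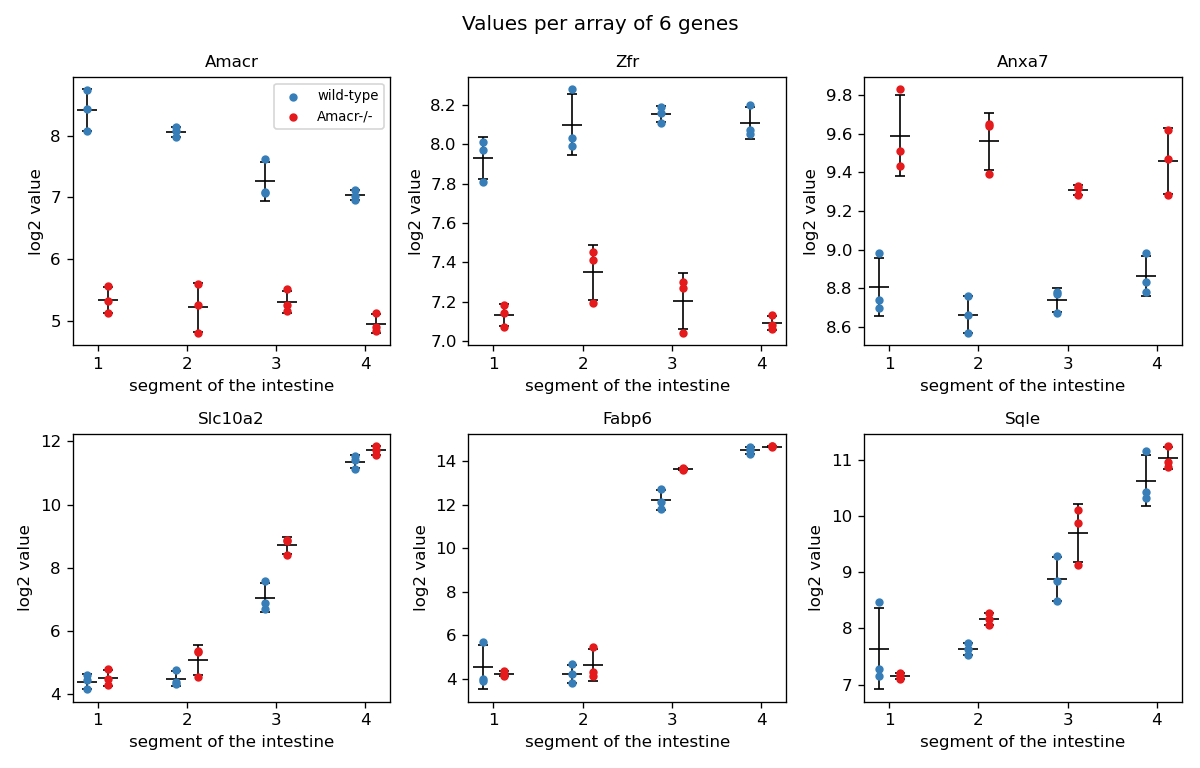
Log2 values of 6 genes (vertical axes) by segment of the intestine (horizontal axes); each dot is 1 array, blue for wild-type and red for Amacr knockout, and black bars give the mean and SD of 3 arrays. The knockout arrays lie below all wild-type arrays of the same segment for Amacr and Zfr, and above them for Anxa7 in segment 1 (difference 0.78).

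In segment 1, 17 genes differed between the genotypes, 5 higher and 12 lower in the knockout. Gclc, which encodes the catalytic subunit of the enzyme that starts glutathione synthesis, rose 2.17-fold, a log2 change of 1.12 (SE 0.20, adjusted p = 0.0299). Anxa7 and Adam2 rose by 0.78 (SE 0.11) and 0.91 (SE 0.15), and Rassf6 and D7Ertd443e by 0.52 and 0.39. The values for Adam2 and D7Ertd443e may be understated, since the wild-type arrays lay at 3.86 to 3.95 and 4.17 to 4.25, near the low end. After Amacr, Slc34a2, a sodium-phosphate cotransporter, fell most, with a change of -2.55 (SE 0.48, adjusted p = 0.0348). Bach2, Denn2b and Zfr changed by -1.21, -1.05 and -0.80 (SE 0.23, 0.19 and 0.09). Exosc9, Ppp1r14d, Gtpbp3, Myo5b and Mrpl15 changed by -0.74, -0.63, -0.59, -0.58 and -0.46. Among the gene lists fixed in advance, that of MHC class II and interferon gamma response fell: 22 of the 23 measured members were lower (median log2 change -0.73), and 0 passed downward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 1.22e-05; adjusted p = 0.759 with an estimated correlation). This list is called the MHC class II list below, though many of its members are other interferon gamma response genes, such as Tap1, Gbp2 and Cxcl9. Ciita and H2-Aa had changes of -0.99 and -1.10, neither past the threshold, and that of H2-Aa was -0.48 without knockout replicate 3. Markers of proliferating cells fell too: 24 of the 26 measured members were lower (median log2 change -0.30), and 0 passed downward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 2.13e-05; adjusted p = 0.759 with an estimated correlation). The lists of xenobiotic metabolism (adjusted p = 0.028) and of the circadian clock (adjusted p = 0.028) rose, with adjusted p = 0.759 and 0.759 with an estimated correlation. The clock list joins genes that share the phase of Dbp with genes that share that of Arntl. Of its 16 measured members, 11 were higher and 5 lower. Cholesterol synthesis was not called here (adjusted p = 0.129): 11 of its 17 measured members were lower, with a mean change of -0.14 that was -0.004 without wild-type replicate 1. Markers of the exocrine pancreas were high in 1 wild-type array of this segment (replicate 1, 2.40 above the mean of all arrays) and 1 knockout array (replicate 3, 1.17 above). Without wild-type replicate 1, 2 or 3, 5, 2 and 29 genes were called, and without knockout replicate 1, 2 or 3, 32, 3 and 5; Amacr and Zfr were called each time. With 1 array left out at a time, the call was kept each time for MHC class II. The call of xenobiotic metabolism was lost without wild-type replicate 1 or knockout replicate 1. The call of circadian clock was lost without wild-type replicate 1 or knockout replicate 3. The call of proliferating cells was lost without wild-type replicate 1, where the mean change was -0.19 in place of -0.44. Without the 5 arrays of the series that were high in pancreas, fat or smooth muscle markers, chosen after seeing the data, 3 genes were called, 2 of them among the 17, and the lists of MHC class II, proliferating cells, xenobiotic metabolism and the clock gave adjusted p = 0.0582, 0.00585, 0.722 and 0.322. Over all alternatives these ranged over 5.64e-08 to 0.759, 1.06e-10 to 0.759, 8.15e-06 to 0.774 and 0.00115 to 0.759. With the 6 arrays of segment 1 alone in the fit, 3 genes were called, 2 of them among the 17, and with array weights, whose estimation stopped before it converged, 349. The other planned genes of sterol and bile acid handling did not pass, with changes from -0.48 (Sqle) to 0.99 (Abca1). Leaving out 1 array moved the change of 10 of the 12 planned genes other than Amacr by over 1.5 times: Sqle then ranged from -0.72 to -0.06 and Abca1 from 0.51 to 1.55.

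In segment 2, 11 genes differed, 6 higher and 5 lower in the knockout. Clca3a1, a chloride channel accessory protein, rose 3.6-fold, a log2 change of 1.85 (SE 0.28, adjusted p = 0.00808). Chac1, an enzyme that degrades glutathione and a target of the unfolded protein response, changed by 1.33 (SE 0.24, adjusted p = 0.0363). Gcnt3, a glycosyltransferase that branches mucin glycans, Ddah1, Anxa7 and Ubr1 rose by 1.07, 0.97, 0.90 and 0.59 (SE 0.19, 0.17, 0.11 and 0.10). Besides Amacr, the genes that fell were Arntl, Denn2b, Zfr and Myo5b. Arntl, a core transcription factor of the circadian clock, changed by -1.55 (SE 0.27, adjusted p = 0.0276), and the others by -1.29, -0.75 and -0.61. The MHC class II list fell: 23 of the 23 measured members were lower (median log2 change -0.71), and 7 passed downward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 3.83e-11; adjusted p = 0.938 with an estimated correlation). Here Cd74 and H2-DMb1 had changes of -1.56 and -2.08, neither past the threshold. Without knockout replicate 3 these were -0.64 and -0.89, and the mean change of the list was -0.53 in place of -0.85. Markers of T cells and intraepithelial lymphocytes and the list of PPARa-regulated oxidation fell (adjusted p = 0.0102 and 0.0209), while markers of Paneth cells, the distal list and the list of sugar and amino acid uptake rose (adjusted p = 0.0209, 0.0243 and 0.0209); all 6 lists of this segment had adjusted p = 0.938 with an estimated correlation. Smooth muscle markers lay 2.30 above the mean of all arrays in wild-type replicate 3 and 1.78 above it in knockout replicate 1, and fat markers 1.66 and 1.08 above. Without the 5 arrays high in such markers, 17 lists were called in segment 2 in place of 6, 5 of them shared. Knockout replicate 3, which stayed in, lay 0.90 above the mean of all arrays for fat and 0.72 above it for smooth muscle markers. Knockout replicate 2 lay at 0.18 and -0.28, and wild-type replicates 1 and 2 at -0.48 and -0.28 and at -0.04 and -0.20. This setting thus left such markers uneven between the genotypes. Without wild-type replicate 1, 2 or 3, 3, 3 and 6 genes were called, and without knockout replicate 1, 2 or 3, 8, 28 and 5; Amacr, Anxa7 and Zfr were called each time. With 1 array left out at a time, the call was kept each time for MHC class II. The call of PPARa-regulated oxidation was lost without wild-type replicate 3 or knockout replicate 1. The call of sugar and amino acid uptake was lost without wild-type replicate 1 or knockout replicate 3. The call of distal genes was lost without wild-type replicate 1 or knockout replicate 2. The call of Paneth cells was lost without knockout replicate 2. The call of T cells was lost without wild-type replicate 1 or knockout replicate 2. With the 6 arrays of segment 2 alone in the fit, 1 gene was called, which was among the 11. The other planned genes of sterol and bile acid handling did not pass, with changes from -0.19 (Nr1h4) to 1.24 (Abca1). Leaving out 1 array moved the change of 9 of the 12 planned genes other than Amacr by over 1.5 times, and Nr1h4 then ranged from -0.44 to 0.06.

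In segment 3, 4 genes differed, 2 higher and 2 lower in the knockout. Slc10a2, the sodium-dependent bile acid transporter of the ileum, rose 3.15-fold, from 7.06 ± 0.47 to 8.71 ± 0.28 (log2, mean ± SD, n = 3), a change of 1.65 (SE 0.23, adjusted p = 0.00472). Ddah1 rose by 1.19 (SE 0.17), and Amacr and Zfr fell. The list of cholesterol synthesis rose: 16 of the 17 measured members were higher (median log2 change 0.34), and 8 passed upward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 5.08e-09; adjusted p = 0.1 with an estimated correlation). Sqle, Cyp51 and Msmo1, enzymes of the later steps of that pathway, had changes of 0.82, 0.82 and 0.67, none past the threshold over all genes. The list of bile acid uptake and FXR rose: 8 of the 16 measured members were higher (median log2 change 0.12), and 3 passed upward when adjusted over the list alone against 1 over all genes (camera, adjusted p = 0.00233; adjusted p = 0.104 with an estimated correlation). Fabp6, the ileal bile acid binding protein, had a change of 1.44 (SE 0.38, adjusted p = 0.383), and Fgf15, the hormone induced by bile acids through FXR, one of -0.71 (SE 0.64, adjusted p = 0.76), which was -0.30 without wild-type replicate 3. Slc10a2, Fabp6, Fgf15 and Slc51b belong to both the bile acid list and the distal list, so the rises of these lists are not separate results. The distal list rose (adjusted p = 0.000191; adjusted p = 0.0681 with an estimated correlation), as did fatty acid synthesis (adjusted p = 3.35e-06; adjusted p = 0.0681 with an estimated correlation), in which Scd1 and Fasn had changes of 1.55 and 1.29, neither past the threshold. Without knockout replicate 3, the array high in fat markers, these were -0.04 and 0.57. The mean change of the fatty acid list was then 0.20 in place of 0.47, so most of its size came from that array. Without knockout replicate 1, Scd1 had a change of 2.47. Markers of fat cells and of fibroblasts rose as well (both adjusted p = 0.0342; both adjusted p = 0.943 with an estimated correlation), as did the lists of oxidative stress response and of sugar and amino acid uptake (both adjusted p = 0.0342; adjusted p = 0.1 and 0.943 with an estimated correlation). Fat markers lay 2.68 above the mean of all arrays in knockout replicate 3 of this segment. Without wild-type replicate 1, 2 or 3, 4, 2 and 10 genes were called, and without knockout replicate 1, 2 or 3, 5, 8 and 2; Amacr and Zfr were called each time. Slc10a2 changed by 1.57 (SE 0.26, adjusted p = 0.0523) without knockout replicate 3, and its call was also lost without wild-type replicate 2 and without the 5 arrays high in markers of other tissues (adjusted p = 0.164). Over all alternatives its adjusted p ranged over 0.000233 to 0.793. With 1 array left out at a time, the call was kept each time for cholesterol synthesis, bile acid uptake, fatty acid synthesis and the distal list. The call of oxidative stress response was lost without wild-type replicate 1 or 2 or knockout replicate 1 or 3. The call of sugar and amino acid uptake was lost without wild-type replicate 1 or 3 or knockout replicate 1 or 3. The call of fibroblasts was lost without wild-type replicate 1 or 2 or knockout replicate 3, and without the last the direction turned (adjusted p = 0.347). The call of fat cells was lost without wild-type replicate 3 or knockout replicate 3, and without the latter the direction turned (adjusted p = 0.574). Without the 5 arrays high in markers of other tissues, the fatty acid synthesis list gave adjusted p = 0.000416, cholesterol synthesis adjusted p = 2.65e-10, fibroblasts adjusted p = 0.0766 and fat cells adjusted p = 0.635, with the direction of the last 2 turned. Over all alternatives these ranged over 5.96e-07 to 0.0681, 2.65e-10 to 0.1, 5.89e-05 to 0.963 and 0.000166 to 0.963. With the 6 arrays of segment 3 alone in the fit, 0 genes were called by limma, with 789 at an unadjusted p under 0.05. With array weights 8 genes were called. The other planned genes of sterol and bile acid handling did not pass, with changes from -0.26 (Abca1) to 0.82 (Sqle). Leaving out 1 array moved the change of 8 of the 12 planned genes other than Amacr by over 1.5 times, and Abca1 then ranged from -0.51 to 0.01.

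In segment 4, 10 genes differed, 4 higher and 6 lower in the knockout. Hao2, a peroxisomal hydroxy acid oxidase, had a rise of 1.00 (SE 0.17, adjusted p = 0.0293), and Anxa7, Gcnt2 and Ets2 rose by 0.59, 0.59 and 0.49. The rise of Hao2 may be understated, since its wild-type values of 4.27 to 4.62 lay near the low end. Dnase1 fell 3.56-fold, a log2 change of -1.83 (SE 0.19, adjusted p = 3.07e-05). Adh6a, an alcohol dehydrogenase, and Hsd17b6, a steroid and retinol dehydrogenase, changed by -1.54 (SE 0.28, adjusted p = 0.0449) and -1.33 (SE 0.23, adjusted p = 0.035), and Zfr and Mical1 by -1.02 and -0.91. The list of cholesterol synthesis rose: 17 of the 17 measured members were higher (median log2 change 0.31), and 0 passed upward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 6.97e-08; adjusted p = 0.516 with an estimated correlation). Its mean change was 0.32, and 0.20 without wild-type replicate 2. The proximal list fell: 13 of the 19 measured members were lower (median log2 change -0.28), and 4 passed downward when adjusted over the list alone against 1 over all genes (camera, adjusted p = 0.000163; adjusted p = 0.668 with an estimated correlation). The list of cholesterol and lipid absorption fell (adjusted p = 0.00606; adjusted p = 0.753 with an estimated correlation), with a median log2 change of -0.09 over 19 members. The planned members Npc1l1, Fabp1, Apoa4 and Apoc3 of this list also belong to the proximal list. Npc1l1, the intestinal cholesterol importer, Abcg5 and Abcg8, which export sterols, and Abca1 had changes of -0.30, -0.35, -0.32 and -0.90 in this segment (SE 0.16, 0.19, 0.25 and 0.41), none past the threshold. The MHC class II list and the markers of B and of T cells fell (adjusted p = 0.000517, 0.0468 and 0.0468; adjusted p = 0.926, 0.926 and 0.986 with an estimated correlation). Fatty acid synthesis and immediate early genes rose (adjusted p = 0.0319 and 0.0348; adjusted p = 0.668 and 0.753 with an estimated correlation). Without wild-type replicate 1, 2 or 3, 12, 4 and 7 genes were called, and without knockout replicate 1, 2 or 3, 3, 17 and 6; Amacr, Dnase1 and Zfr were called each time. With 1 array left out at a time, the call was kept each time for cholesterol synthesis. The call of lipid absorption was lost without wild-type replicate 3 or knockout replicate 1 or 2. In wild-type replicate 3 the mean of that list was -0.35 against all arrays, and -0.91 and -0.62 in wild-type replicates 1 and 2. The call of fatty acid synthesis was lost without wild-type replicate 2 or 3 or knockout replicate 2. The call of MHC class II was lost without wild-type replicate 1 or knockout replicate 1. The call of immediate early genes was lost without wild-type replicate 1 or 2 or knockout replicate 1 or 2. The call of proximal genes was lost without wild-type replicate 3. Its mean of that list was -0.61, against -1.43 and -1.10 in wild-type replicates 1 and 2, so part of the size of both falls rests on that array. The call of B cells was lost without wild-type replicate 2 or 3 or knockout replicate 1 or 3. The call of T cells was lost without wild-type replicate 1 or 2 or knockout replicate 1 or 3. Without the 5 arrays high in markers of other tissues, 4 genes were called, 3 of them among the 10, and with the 6 arrays of segment 4 alone in the fit, 3, with 2 among the 10. None of those 5 arrays belongs to segment 4, so its log2 changes stayed the same without them. Only the spread and degrees of freedom of the pooled fit differed. With array weights 127 genes were called. The other planned genes of sterol and bile acid handling did not pass, with changes from -0.85 (Fgf15) to 0.43 (Slc51a). Leaving out 1 array moved the change of 8 of the 12 planned genes other than Amacr by over 1.5 times: Fgf15 then ranged from -2.00 without knockout replicate 3 to -0.10 without knockout replicate 2, Abcg5 from -0.45 to -0.20 and Abcg8 from -0.51 to -0.09.

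Averaged over the 4 segments per replicate number, 4 genes differed. Amacr and Zfr fell, by changes of -2.49 (SE 0.10, adjusted p = 0.000357) and -0.88 (SE 0.06, adjusted p = 0.00736), and Gcnt3 and Anxa7 rose by 0.72 (SE 0.05, adjusted p = 0.00973) and 0.71 (SE 0.06, adjusted p = 0.0237). With array weights, whose estimation stopped before it converged, 707 genes were called. Slc10a2 had a change of 0.68 (SE 0.07, adjusted p = 0.0639) and did not pass. The sterol transporters had small changes: -0.04 for Npc1l1, -0.10 for Abcg5 and 0.01 for Abcg8 (SE 0.10, 0.13 and 0.20), and all 3 turned sign when 1 replicate or another was left out. The bile acid exporter subunits Slc51a and Slc51b had changes of 0.41 and 0.12, and the nuclear receptors Nr1h4 (FXR) and Nr0b2 (SHP) of 0.11 and 0.16, none past the threshold. With 1 replicate left out, Nr1h4 ranged from -0.04 to 0.21, Nr0b2 from 0.01 to 0.27 and Slc51b from 0.003 to 0.30, and with array weights Nr0b2 turned to -0.04. The MHC class II list fell: 23 of the 23 measured members were lower (median log2 change -0.53), and 0 passed downward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 1.6e-09; adjusted p = 0.465 with an estimated correlation). The list of cholesterol synthesis rose: 15 of the 17 measured members were higher (median log2 change 0.16), and 2 passed upward when adjusted over the list alone against 0 over all genes (camera, adjusted p = 2.14e-05; adjusted p = 0.435 with an estimated correlation). Markers of Paneth cells rose (camera, adjusted p = 0.000191, and adjusted p = 0.496 with an estimated correlation). In every comparison this list rests on 7 measured members of 16 planned. In the mean all 7 were higher, with an estimated correlation between members of 0.777. In all, 13 of 38 lists were called, 10 higher and 3 lower, and 0 with an estimated correlation or with fry. The other rises were those of bile acid uptake, fatty acid synthesis, xenobiotic metabolism, oxidative stress response, sugar and amino acid uptake, circadian clock, the distal list and goblet cells (adjusted p = 0.0078, 0.00333, 0.0187, 0.0373, 0.0297, 0.0187, 0.0207 and 0.0355; adjusted p = 0.435, 0.435, 0.832, 0.435, 0.828, 0.435, 0.435 and 0.435 with an estimated correlation). The other falls were those of PPARa-regulated oxidation and B cells (adjusted p = 0.0355 and 0.00333; adjusted p = 0.757 and 0.435 with an estimated correlation). Cholesterol synthesis had mean changes of -0.14, 0.15, 0.37 and 0.32 in segments 1 to 4, the first of them -0.004 without wild-type replicate 1. Fatty acid synthesis had one of -0.10 in segment 1, which was -0.01 without that array. Paneth cells and the distal list also ran against their mean in segment 1 (both -0.04), B cells in segment 3 (0.10) and PPARa-regulated oxidation in segment 4 (0.03). For B cells in segment 3, knockout replicate 3 lay at 1.11 and knockout replicates 1 and 2 at -0.33 and -0.56. Without wild-type replicate 1, 2 or 3, 4, 1 and 4 genes were called, and without knockout replicate 1, 2 or 3, 1, 1 and 4; Amacr was called each time. With 1 replicate left out at a time, the call was kept each time for cholesterol synthesis, bile acid uptake, fatty acid synthesis, MHC class II and Paneth cells. The mean change of MHC class II was -0.28 in place of -0.52 without wild-type replicate 1, that of fatty acid synthesis 0.08 in place of 0.16 without knockout replicate 3, and that of Paneth cells 0.19 in place of 0.39 without knockout replicate 2. Wild-type replicate 1 was the highest wild-type array for MHC class II in segments 1 to 4 (0.80, 0.80, 0.73 and 0.66). If the number marks 1 mouse, the falls of that list in several segments are not separate results. All list calls with a replicate or array left out used the preset correlation. The call of PPARa-regulated oxidation was lost without wild-type replicate 2 or 3 or knockout replicate 2. The call of xenobiotic metabolism was lost without wild-type replicate 1, where the direction turned (adjusted p = 0.833), or knockout replicate 1. The call of oxidative stress response was lost without knockout replicate 2 or 3. The call of sugar and amino acid uptake was lost without wild-type replicate 1 or knockout replicate 1 or 3. The call of circadian clock was lost without wild-type replicate 1, and of its 16 measured members 10 were higher and 6 lower over all replicates. The call of distal genes was lost without wild-type replicate 1. The call of goblet cells was lost without wild-type replicate 1 or knockout replicate 1 or 2. The call of B cells was lost without wild-type replicate 2 or knockout replicate 2. The other planned genes of sterol and bile acid handling did not pass, with changes from -0.33 (Fgf15) to 0.43 (Fabp6). Leaving out 1 replicate moved the change of 9 of the 12 planned genes other than Amacr by over 1.5 times, and Fgf15 then ranged from -0.61 to -0.16.

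Whether the genotype difference varied by segment was tested for every gene with the interaction of genotype and segment. No gene passed: 0 of 15267 were called by limma's moderated F test, with 907 at an unadjusted p under 0.05 and a smallest adjusted p of 0.487, for Clca3a1. With array weights 2 genes were called, and without wild-type replicate 3, 3 genes. A call in one segment and not in another is therefore not shown to differ between them. Of 31 genes called in at least 1 segment, 2 were called in all 4 segments (Amacr and Zfr), 1 in 3 segments (Anxa7), 3 in 2 segments and 25 in 1 segment, and 21 of the 31 changed with the same sign in all 4. The segments may come from the same mice, so the shared signs are not independent support for these calls.

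**Figure D2:**
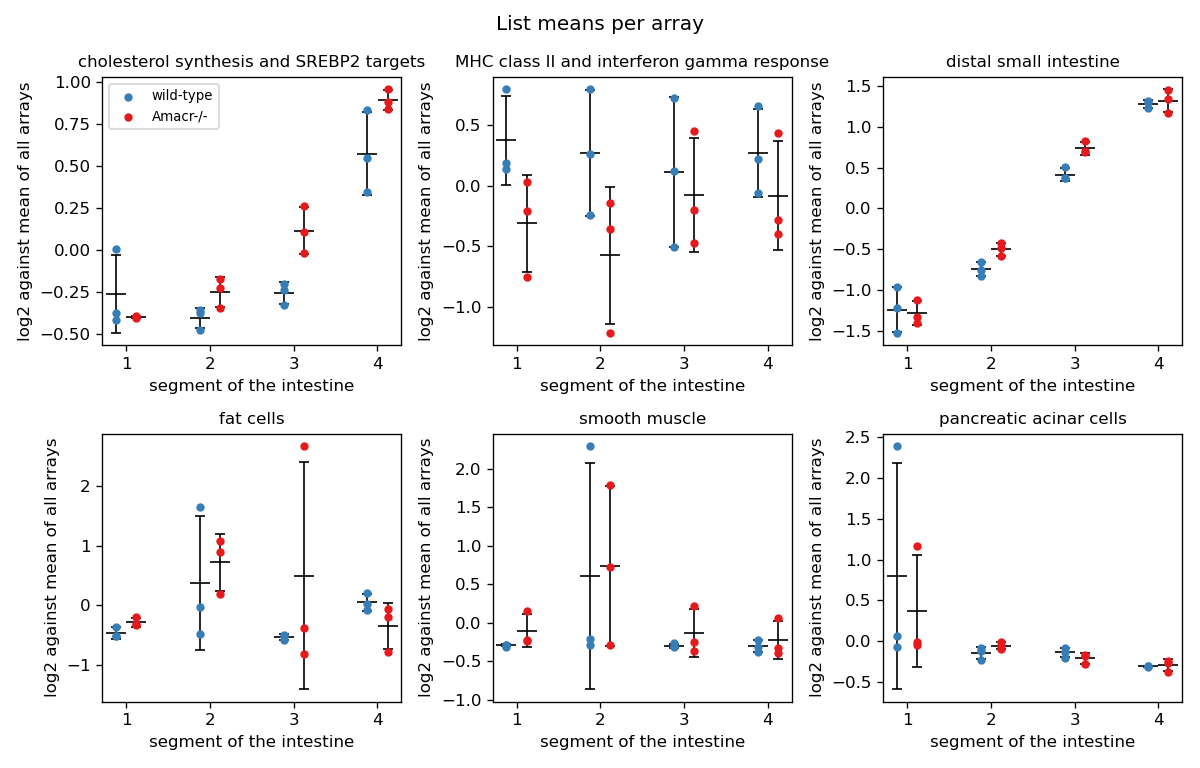
Mean over the members of 6 gene lists (vertical axes, log2 against each gene's mean over all 24 arrays) by segment (horizontal axes); each dot is 1 array, blue for wild-type and red for Amacr knockout, and black bars give the mean and SD of 3 arrays. The arrays that stand apart for fat, smooth muscle and pancreas markers include 1 knockout array of segment 3 at 2.68 for fat.

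Along the wild-type intestine, 3601 genes differed between segment 4 and segment 1, 1530 higher and 2071 lower in segment 4. Fabp6 and Slc10a2 rose by 9.97 (SE 0.38, adjusted p = 5.44e-13) and 6.95 (SE 0.23, adjusted p = 1.02e-13) on the log2 scale. These changes may be understated. The values of segment 1, 3.89 to 5.69 for Fabp6 and 4.15 to 4.60 for Slc10a2, lay near the low end of the arrays, without a detection call. The same holds for the genes named here and in the next paragraph with an array below 4.74, the 25th percentile of all values: Mgat4c, Saa1, Prss23 and Gsdmc2 in segment 1, and Onecut2, Cyp4a10, Ces2g, Pdk4 and Scarb1 in segment 4. In 4 of the 6 arrays of segment 4 Fabp6 was the highest value. Mgat4c, Tmigd1, Suox and Plb1 rose by 6.55, 6.07, 5.32 and 5.30, and Saa1, Prss23, Gsdmc2 and ccdc198 by 5.45, 5.08, 4.33 and 4.00. Changes are segment 4 minus segment 1 here. Reg1 and the alkaline phosphatase Akp3 fell most, with changes of -7.25 (SE 0.56, adjusted p = 1.29e-08) and -7.01 (SE 0.90, adjusted p = 7.92e-06). S100g, a calcium-binding protein, Onecut2, Otop3, Cyp4a10, Ces2g, Pdk4, Adh4 and Aadac changed by -5.85, -5.49, -5.40, -5.05, -4.93, -4.88, -4.82 and -4.71. The distal list rose: 15 of the 16 measured members were higher (median log2 change 2.13), and 14 passed upward when adjusted over the list alone against 14 over all genes (camera, adjusted p = 7.54e-14; adjusted p = 0.00043 with an estimated correlation). The proximal list fell: 17 of the 19 measured members were lower (median log2 change -2.29), and 15 passed downward when adjusted over the list alone against 15 over all genes (camera, adjusted p = 9.71e-13; adjusted p = 0.0203 with an estimated correlation). Peroxisomal genes fell, among them Slc27a2 (-3.27) and Ehhadh (-1.29): 23 of the 26 measured members were lower (median log2 change -0.67), and 20 passed downward when adjusted over the list alone against 19 over all genes (camera, adjusted p = 4.71e-12; adjusted p = 0.0269 with an estimated correlation). Goblet cell markers rose, among them Agr2 (1.38) and Klk1 (1.25): 11 of the 11 measured members were higher (median log2 change 0.96), and 11 passed upward when adjusted over the list alone against 11 over all genes (camera, adjusted p = 3.36e-11; adjusted p = 0.00823 with an estimated correlation).

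Cholesterol synthesis rose, with Sqle at 2.99 and Fdft1 at 2.02 (adjusted p = 1.21e-06; adjusted p = 0.165 with an estimated correlation). Cholesterol and lipid absorption fell, with Scarb1 at -3.81 and Cd36 at -3.29 (adjusted p = 1.45e-07; adjusted p = 0.0891 with an estimated correlation). Xenobiotic metabolism fell, with Cyp2b10 at -4.07 (adjusted p = 4.71e-12; adjusted p = 0.165 with an estimated correlation). In all, 16 of 38 lists were called, and 4 with an estimated correlation: the distal, proximal, peroxisomal and goblet lists. Markers of T cells fell, with Klrd1 at -1.76 and Gzmb at -1.46, and so did the type I interferon response, with Usp18 at -2.04 (adjusted p = 0.000875 and 0.00182; adjusted p = 0.548 and 0.548 with an estimated correlation). Proliferating and crypt stem cell markers rose, with Top2a at 1.45 and Axin2 at 1.31 (adjusted p = 5.59e-06 and 0.00931; adjusted p = 0.541 and 0.335 with an estimated correlation). Paneth cell markers rose, with Ang4 at 3.76, as did the unfolded protein response and enterocyte markers (adjusted p = 0.0467, 0.0287 and 0.0303; adjusted p = 0.548, 0.541 and 0.303 with an estimated correlation). PPARa-regulated oxidation and pancreas markers fell (adjusted p = 7.18e-05 and 0.00182; adjusted p = 0.179 and 0.541 with an estimated correlation), with wild-type replicate 1 of segment 1 at 2.40 above the mean of all arrays for pancreas markers. Of the hormone genes, Nts and Pyy rose by 3.38 and 2.48, and Cck and Gip changed by -2.89 and -2.67, while the list of enteroendocrine cells was not called. With 1 array left out at a time, the call was kept each time for cholesterol synthesis, lipid absorption, peroxisomal oxidation and biogenesis, PPARa-regulated oxidation, xenobiotic metabolism, type I interferon response, the proximal list, the distal list, goblet cells, crypt stem cells, proliferating cells and T cells. The call of unfolded protein response was lost without wild-type replicate 2 of segment 1 or wild-type replicate 1 of segment 4. The call of absorptive enterocytes was lost without wild-type replicate 1 of segment 1 or wild-type replicate 3 of segment 4. The call of Paneth cells was lost without wild-type replicate 2 or 3 of segment 1 or wild-type replicate 2 of segment 4. The call of pancreatic acinar cells was lost without wild-type replicate 1 of segment 1.

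Between neighbouring segments of the wild-type intestine, 135 genes differed from segment 1 to 2, 314 from segment 2 to 3 and 687 from segment 3 to 4. From segment 1 to 2, Npl, Osr2 and Nts rose by 2.65, 2.56 and 2.46, and Akp3, the iron exporter Slc40a1 and Slc16a9 changed by -5.00, -4.14 and -3.56. From segment 2 to 3, Fabp6, Plb1 and Mgat4c rose by 7.98, 5.71 and 4.24, and Reg1, Onecut2 and Ces1f changed by -4.11, -3.36 and -2.71. From segment 3 to 4, Slc10a2, Slc13a1 and Slc6a14 rose by 4.30, 3.39 and 3.30, and Cyp2b10, Enpp3 and Aadac changed by -3.01, -2.90 and -2.71. Of these values, those of Osr2, Fabp6, Mgat4c and Slc6a14 may be understated, with arrays below 4.74 in the first segment of the step (lowest values 4.59, 3.80, 4.50 and 3.81). Without the 5 arrays high in markers of other tissues, 52 genes differed from segment 1 to 2. With array weights the 3 counts were 445, 675 and 2158. With 1 array left out, the count from segment 1 to 2 was 84 without replicate 2 of segment 1, 67 without replicate 3 of segment 1, 79 without replicate 2 of segment 2 and 59 without replicate 3 of segment 2. Likewise, the count from segment 2 to 3 was 152 without replicate 1 of segment 2, 119 without replicate 2 of segment 2, 159 without replicate 1 of segment 3 and 201 without replicate 2 of segment 3, and the count from segment 3 to 4 was 436 without replicate 1 of segment 3, 340 without replicate 2 of segment 3, 302 without replicate 1 of segment 4 and 338 without replicate 2 of segment 4. In the knockout, 4633 genes differed between segment 4 and segment 1, 2355 higher and 2278 lower. Of these, 2769 were also called in the wild-type, 2768 in the same direction, from arrays that the 2 comparisons do not share. Independent lists of these sizes would share 236 genes that rose and 309 that fell, against 1175 and 1593 observed. Over all genes the log2 changes correlated at r = 0.916, which is across genes that are not independent replicates.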

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

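The tests of lists in this part, those of the clock phase, of the nearest neighbours, of the probe variant and of the change of Slc10a2 without 1 array were chosen after the results were seen. With groups of 3, no array was tested as an outlier. The genotype differences of 9 gene lists in segments 2, 3 or 4 differed from those in segment 1, by camera over 114 tests at a preset correlation; 0 of these hold with an estimated correlation. For cholesterol synthesis and SREBP2 targets, the difference of differences was 0.29 in segment 2 (0.16 to 0.37 with 1 array left out, adjusted p = 0.00129; adjusted p = 0.986 with an estimated correlation), 0.51 in segment 3 (0.38 to 0.59 with 1 array left out, adjusted p = 3.49e-06; adjusted p = 0.667 with an estimated correlation), 0.46 in segment 4 (0.32 to 0.58 with 1 array left out, adjusted p = 7.98e-06; adjusted p = 0.668 with an estimated correlation). For distal small intestine, the difference of differences was 0.29 in segment 2 (0.15 to 0.43 with 1 array left out, adjusted p = 0.0152; adjusted p = 0.667 with an estimated correlation), 0.37 in segment 3 (0.23 to 0.51 with 1 array left out, adjusted p = 0.00434; adjusted p = 0.667 with an estimated correlation). For proliferating cells, the difference of differences was 0.52 in segment 2 (0.27 to 0.78 with 1 array left out, adjusted p = 7.98e-06; adjusted p = 0.986 with an estimated correlation), 0.56 in segment 3 (0.31 to 0.82 with 1 array left out, adjusted p = 7.07e-05; adjusted p = 0.986 with an estimated correlation), 0.40 in segment 4 (0.15 to 0.65 with 1 array left out, adjusted p = 0.0107; adjusted p = 0.986 with an estimated correlation). For T cells and intraepithelial lymphocytes, the difference of differences was -0.24 in segment 2 (-0.37 to -0.10 with 1 array left out, adjusted p = 0.0368; adjusted p = 0.986 with an estimated correlation). For pancreatic acinar cells, the difference of differences was 0.52 in segment 2 (-0.28 to 0.95 with 1 array left out, adjusted p = 0.0324; adjusted p = 0.986 with an estimated correlation). For fatty acid synthesis, the difference of differences was 0.57 in segment 3 (0.29 to 0.72 with 1 array left out, adjusted p = 0.000385; adjusted p = 0.667 with an estimated correlation), 0.21 in segment 4 (0.12 to 0.30 with 1 array left out, adjusted p = 0.0454; adjusted p = 0.986 with an estimated correlation). For MHC class II and interferon gamma response, the difference of differences was 0.50 in segment 3 (0.18 to 0.80 with 1 array left out, adjusted p = 0.0324; adjusted p = 0.986 with an estimated correlation). For cholesterol and lipid absorption, the difference of differences was -0.39 in segment 4 (-0.53 to -0.25 with 1 array left out, adjusted p = 0.000767; adjusted p = 0.896 with an estimated correlation). For proximal small intestine, the difference of differences was -0.54 in segment 4 (-0.73 to -0.32 with 1 array left out, adjusted p = 0.000718; adjusted p = 0.896 with an estimated correlation). Part of each value comes from segment 1, where the mean changes were -0.14 for cholesterol synthesis, -0.04 for the distal list, -0.44 for proliferating cells, 0.03 for T cells, -0.43 for pancreas, -0.10 for fatty acid synthesis, -0.69 for MHC class II, 0.17 for lipid absorption and 0.16 for the proximal list. Leaving out 1 array moved the differences of differences by over 1.5 times for all but cholesterol synthesis in segments 3 and 4. Without wild-type replicate 1 of segment 1 the changes in segment 1 were -0.004 for cholesterol synthesis, -0.19 for proliferating cells, -0.01 for fatty acid synthesis and 0.37 for pancreas, so the differences between segments for these lists rest in part on that array. Without knockout replicate 3, the change of fatty acid synthesis in segment 3 was 0.20 in place of 0.47. For MHC class II in segment 3, the lowest and highest values came without wild-type replicates 3 and 1 of that segment. All of these share the arrays of segment 1, in 2 of which pancreas markers were high.

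The clock list rose in segment 1 at the preset correlation (adjusted p = 0.028; adjusted p = 0.759 with an estimated correlation), a call lost without wild-type replicate 1 or knockout replicate 3, and Arntl fell in segment 2. Dbp had a mean change of 2.24 and Arntl of -1.15 over the 4 segments (adjusted p = 0.247 and 0.225, neither past the threshold). The median change of 10 genes that share the phase of Dbp lay 0.914 log2 above that of 5 genes that share the phase of Arntl, with an SD between replicate numbers of 0.311, and all 3 knockout scores lay above all 3 wild-type scores, as chance gives for 10% of scores in either direction; without Dbp and Arntl the difference was 0.823. The tables argue against fat, muscle or pancreas RNA as the cause, since the difference was 0.974 without the 5 arrays high in those markers. A difference in clock phase, such as another time of day at collection, may account for the pattern. The hours of collection were not used here, so such a difference and an effect of the genotype on the clock both stay open.

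Zfr and Sub1, the genes 6 and 5 places from Amacr among measured genes of chromosome 15, were called lower in the knockout, Zfr in all 4 segments and Sub1 in segment 1. They are 2 of the 50 nearest measured genes, against 28 of 15216 others (Fisher's exact test, two-sided p = 0.00431), but these same genes gave rise to the idea, so the test decides nothing. Among the other 48 neighbours, 4 had an unadjusted p under 0.05 in the mean of 4 segments, against 1183 of 15216 other genes (Fisher's exact test, two-sided p = 0.787). DNA of another strain kept beside the targeted allele may lower these genes, and a strain variant under the probes might lower the signal alone; the fold of Zfr did not differ detectably between segments (limma's moderated F test on n = 24 arrays, unadjusted p = 0.164), which both allow. These and an effect of the genotype cannot be told apart here, since no sequence of the mice was analysed.

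In segment 3 Slc10a2 rose, as did the distal list at the preset correlation (adjusted p = 0.000191; adjusted p = 0.0681 with an estimated correlation), while Fabp6 did not pass (adjusted p = 0.383) and Fgf15 had a change of -0.71 (-0.30 without wild-type replicate 3). Slc10a2, Fabp6 and Fgf15 are themselves members of the distal list, and Slc10a2 was its only called member. The tables argue against fat RNA in 1 knockout array as the whole cause, since Slc10a2 changed by 1.57 without that array (SE 0.264), though its adjusted p became 0.0523 with fewer arrays. If knockout segment 3 lay further down the intestine, all genes graded between segments 2 and 4 should move together: 84.4% of 603 such genes moved toward segment 4, by a median of 0.158 of their gradient against 0.241 for Slc10a2. The share of Slc10a2 may be too high, since its values in wild-type segment 2 (4.33 to 4.77) lay near the low end of the arrays. The median shares of the 3 knockout arrays ranged from 0.104 to 0.219, on both sides of the limit of 0.121. The rule for this limit was set in advance, but its value was computed from the share of Slc10a2 in these same arrays. A shift of the segment's position may thus account for the pattern, and it cannot be told apart from an effect of the genotype, since where each segment was divided from the next is known only from the division into equal parts. From wild-type segment 3 to 4, the mean of cholesterol synthesis went from -0.258 to 0.575. That of the proximal list went from -0.147 to -1.048, and that of lipid absorption from 0.017 to -0.625. Their genotype differences in segment 4 ran the same way (0.318, -0.376 and -0.223), as did that of cholesterol synthesis in segment 3 (0.373). The distal list differed by 0.039 in segment 4. A shift of position was not tested in segment 4 or for cholesterol synthesis, and stays open there.

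Each comparison of 3 samples with 3 allows 10 splits, too few for a share under 0.05; the counts of splits as large include the real one. Between the genotypes, the real split and the highest other split called, in genes, 17 against 0 in segment 1 (1 of 10 splits as large), 11 against 36 in segment 2 (2 of 10 splits as large), 4 against 2 in segment 3 (1 of 10 splits as large), 10 against 9 in segment 4 (1 of 10 splits as large), 4 against 10 in the mean of 4 segments (2 of 10 splits as large). Between the genotypes, the real split and the highest other split called, in lists, 4 against 10 in segment 1 (9 of 10 splits as large), 6 against 10 in segment 2 (7 of 10 splits as large), 8 against 18 in segment 3 (9 of 10 splits as large), 8 against 17 in segment 4 (7 of 10 splits as large), 13 against 20 in the mean of 4 segments (4 of 10 splits as large). Between segments the gene counts were 3601 against 4 for segment 4 against 1 in the wild-type, 4633 against 0 for the same in the knockout, 135 against 1 for segment 2 against 1, 314 against 0 for segment 3 against 2, 687 against 0 for segment 4 against 3, with 1 of 10 splits as large in each, and the list count of segment 4 against 1 was 16 against 18 (2 of 10). In the other splits of 2 segments, each group mixed arrays of both, so a large real difference widened the spread within groups. Their low gene counts are thus no separate support. For the interaction the counts were 0 and 1 (10 of 10). In segment 2, 1 other split called more genes than the real one, 36, and in the mean 1 other split called 10. The reason was not tested. The list counts of other splits passed the real ones in every comparison tested for lists.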

How the results depend on the processing

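The alternatives without the 5 arrays, with marker means as covariates and with all probe sets were chosen after the data were seen. For named genes and called lists, 4385 values under alternatives kept direction and side of the threshold, 559 kept direction and lost the call, 6 gained one and 61 turned direction. For lists the value given is an adjusted p, for genes a log2 change. The cause was not tested, except that fewer arrays or genes enter some fits. These counts pool planned genes without a call, which cannot lose one, and large changes along the wild-type intestine, so they do not measure how stable the genotype calls were. Of the genes called between genotypes, 2 of 17, 3 of 11, 2 of 4 and 3 of 10 in segments 1 to 4 were called with each array left out. In the mean of 4 segments, 1 of 4 was called with each replicate left out. With renewed quantile normalization, the counts were 10 for segment 1 (reported 17); direction turned for Abcg8, mean of 4 segments (-0.00667). Without genes below the lower of the 2 limits on dim genes, the counts were 4 for lists, segment 3 (reported 8). Without genes below the median, the counts were 18 for segment 2 (reported 11). With array weights, whose estimation stopped before it converged, the counts were 349 for segment 1 (reported 17), 8 for segment 3 (reported 4), 127 for segment 4 (reported 10), 707 for mean of 4 segments (reported 4), 2 for the interaction (reported 0), 445 for segment 2 against 1, wild-type (reported 135), 675 for segment 3 against 2, wild-type (reported 314), 2158 for segment 4 against 3, wild-type (reported 687); direction turned for Slc51b, segment 1 (0.0642), Npc1l1, segment 3 (-0.0144), Abcg8, segment 3 (-0.102), Abcg8, mean of 4 segments (-0.11), Nr0b2, mean of 4 segments (-0.0367). With the 6 arrays of a segment alone, the counts were 3 for segment 1 (reported 17), 1 for segment 2 (reported 11), 0 for segment 3 (reported 4), 3 for segment 4 (reported 10). With an estimated correlation, the counts were 0 for lists, segment 1 (reported 4), 0 for lists, segment 2 (reported 6), 0 for lists, segment 3 (reported 8), 0 for lists, segment 4 (reported 8), 0 for lists, mean of 4 segments (reported 13), 4 for lists, segment 4 against 1, wild-type (reported 16). With fry, the counts were 0 for lists, segment 1 (reported 4), 0 for lists, segment 2 (reported 6), 2 for lists, segment 3 (reported 8), 0 for lists, segment 4 (reported 8), 0 for lists, mean of 4 segments (reported 13). Without the 5 arrays high in markers of other tissues, the counts were 3 for segment 1 (reported 17), 2 for segment 3 (reported 4), 4 for segment 4 (reported 10), 52 for segment 2 against 1, wild-type (reported 135), 17 for lists, segment 2 (reported 6); direction turned for Abcg8, segment 1 (-0.285), Slc51b, segment 1 (0.04), Npc1l1, segment 2 (0.005), Fabp6, segment 2 (-0.225), Nr0b2, segment 2 (0.07), Nr1h4, segment 2 (0.035), Abcg8, segment 3 (-0.025), Abca1, segment 3 (0.0117), Abcg8, mean of 4 segments (-0.0426), Abca1, mean of 4 segments (-0.00569), fibroblasts and connective tissue, segment 3 (0.0766), fat cells, segment 3 (0.635). With marker means as covariates, the counts were 4 for segment 1 (reported 17), 6 for segment 4 (reported 10); direction turned for Slc51b, segment 1 (0.00683), Abcg8, segment 3 (-0.032), Abca1, segment 3 (0.0097). None of the 5 arrays left out for such markers belongs to segment 4. Its lower gene count without them thus came only from the spread and degrees of freedom of the pooled fit. The signal near background limits dim genes, for which no detection call was used.

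With each replicate left out, counts ranged as follows: segment 1 2 to 32, segment 2 against 1, wild-type 59 to 125, lists, segment 1 2 to 7, segment 2 3 to 28, segment 3 against 2, wild-type 119 to 319, lists, segment 2 5 to 14, segment 3 2 to 10, segment 4 against 3, wild-type 302 to 930, segment 4 3 to 17, lists, segment 4 5 to 9, mean of 4 segments 1 to 4, the interaction 0 to 3, lists, mean of 4 segments 11 to 20. Values of genes and lists whose direction turned ranged as follows: Npc1l1, segment 1 -0.0933 to 0.207, Abcg5, segment 1 -0.243 to 0.163, Abcg8, segment 1 -0.112 to 0.323, Slc10a2, segment 1 -0.02 to 0.235, Fabp6, segment 1 -0.615 to 0.285, Slc51b, segment 1 -0.22 to 0.035, Npc1l1, segment 2 -0.162 to 0.0583, Abcg5, segment 2 -0.075 to 0.12, Abcg8, segment 2 -0.105 to 0.325, Fabp6, segment 2 -0.0133 to 0.662, Fgf15, segment 2 -0.105 to 0.0233, Slc51b, segment 2 -0.3 to 0.07, Nr0b2, segment 2 -0.283 to 0.187, Nr1h4, segment 2 -0.44 to 0.055, Npc1l1, segment 3 -0.0133 to 0.202, Abcg5, segment 3 -0.115 to 0.01, Abcg8, segment 3 -0.12 to 0.165, Abca1, segment 3 -0.508 to 0.0117, fibroblasts and connective tissue, segment 3 5.89e-05 to 0.347, fat cells, segment 3 0.000166 to 0.574, Nr0b2, segment 4 -0.0717 to 0.363, Npc1l1, mean of 4 segments -0.143 to 0.0267, Abcg5, mean of 4 segments -0.221 to 0.0075, Abcg8, mean of 4 segments -0.21 to 0.162, Nr1h4, mean of 4 segments -0.0421 to 0.212, xenobiotic and drug metabolism, mean of 4 segments 1.85e-05 to 0.833.

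Samples of the genotypes share only a number: 2 of 12 pairs of the same number and segment correlated over 0.1 in their deviations from the group means (-0.24 to 0.29), and 3 of 24 arrays correlated best with their own number. Across segments within a genotype, 15 of 36 pairs did (-0.29 to 0.52), and 36 of 72 array and segment combinations correlated best with their own number; the labels do not say that a number marks 1 mouse. With the number within genotype as a fixed block, the counts were 481 for segment 3 against 2, wild-type (reported 314). With the number shared by the genotypes as a fixed block, the counts were 0 for segment 1 (reported 17), 0 for segment 2 (reported 11), 0 for segment 3 (reported 4), 5 for segment 4 (reported 10), 0 for mean of 4 segments (reported 4). With 24 arrays, a segment term and a random block, the counts were 131 for mean of 4 segments (reported 4). A random block for the number within genotype in the fit of 8 groups, which does not cover the mean of 4 segments, moved no count by over 1.5 times.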
